A study of Homo sapiens with 12 samples.

How the data were processed

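Total RNA of 2 estrogen receptor-positive human breast cancer cell lines, each kept long term without estrogen, was hybridised to Affymetrix 3′ expression arrays with 54675 probe sets. Per the labels' protocols, cells were seeded in triplicate dishes, washed on the next day and given medium with 10% dextran-coated charcoal-treated serum and either 0.1% ethanol or 1 µM fulvestrant, and RNA was harvested after 48 h. RNA was extracted with Trizol, cleaned on RNeasy columns with DNase and labelled with the one-cycle kit, per the labels' protocols. The 12 arrays fall into 4 groups of 3. The replicates are dishes of the same seeding design, so p-values measure the spread between such dishes and arrays.

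The authors deposited log2 expression values per probe set. They were made with RMA in Affymetrix Expression Console, per the submitters' processing notes, and the version is not given in the sources used here. RMA corrects the background, normalizes arrays by quantiles and summarises the probes of a set by median polish. The values themselves show that the lines were not brought to a common distribution. The mean gap between the sorted values of 2 arrays was at most 0.0608 within a line and between 0.332 and 0.357 across the lines. No batch label is given. The spiked-in poly-A controls were lower by a log2 difference of -2.54 and the 18S rRNA controls by -2.17 in HCC-1428/LTED than in MCF-7/LTED, so for the comparison between lines a difference of processing and the line cannot be told apart. The comparisons of fulvestrant with ethanol lie within a line. The difference between these changes sets the lines against each other, so the same limit holds for it. Array values carry no read depth, and the number of arrays limits their precision.

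Probe sets were named through the platform annotation and the gene identifiers of the RefSeq annotation of GRCh38.p14, which was used for names and for the order of genes along chromosomes. A single symbol was found for 41091 probe sets, several symbols for 1801, and 11777 probe sets were unlisted and stay unnamed here. The 62 array control probe sets were left out. No genes were named from probe sets with several symbols. Each of the 19775 named genes was represented by its probe set with the highest mean over all 12 arrays, without a filter on dim probe sets. List members were matched by current or older symbol, and those without a named probe set were left out, so that 30 of 32 estrogen-induced and 53 of 55 E2F target genes were measured, for example.

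Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a group-means model of all 12 arrays, so that the groups share the estimate of each gene's spread. The contrasts were fulvestrant minus ethanol in each line, the difference between these changes (HCC-1428/LTED minus MCF-7/LTED), and HCC-1428/LTED minus MCF-7/LTED under ethanol. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Genes past a log2 change of 1 in size are counted beside each total. Genes that changed the same way in both lines are those past the threshold in each with the same sign. The controls are separate arrays in the lines.

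A total of 19 gene lists, taken from textbook knowledge, were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives unless said otherwise. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists of a contrast. The alternatives were an estimated correlation and fry. Camera asks whether a list's genes moved up or down relative to other genes, and fry whether the list's genes move on balance in a single direction. A list whose genes moved both ways can therefore lack a call however much they changed. The rule for named genes allowed a fixed panel of 15 genes, the 10 largest rises and 10 largest falls of each fulvestrant comparison among genes past the threshold whose groups of arrays did not overlap, up to 4 members of each list (the 2 largest rises and 2 largest falls past the threshold, or else the member with the smallest p), the 5 most positive and 5 most negative differences between the lines, the 5 shared rises and 5 shared falls that were largest in the line where they were smaller, and the 5 genes highest in each line under ethanol. Genes without a symbol and those with locus, open reading frame or antisense names were skipped, as were a few sex-linked transcripts. The text names part of the genes that the rule allows, and 5 further genes chosen after their values were seen. RNA quality was read from the 3′ minus 5′ log2 difference of the ACTB and GAPDH control probe sets, with exact two-sided permutation tests, whose smallest p for 3 against 3 arrays is 0.1.

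The alternatives were the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, centring each array on its median, quantile normalization of all 12 arrays together, leaving out the dimmest 40% of genes, an intensity trend with robust variance, array weights, the replicate number as a block, fitting each line alone, and leaving out each array in turn. Replicate pairs of a group had Pearson correlations across genes of 0.9969 to 0.9979, and at most 213 of 54675 values were identical between 2 arrays, so no array was a copy of another.

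The gene tests were tested on simulated data built from the real ethanol group means and the spreads of 19775 genes, 200 of them changed, with noise drawn independently for each gene. At a log2 change of 0.5, 85.1% of the changed genes were recovered for fulvestrant in MCF-7/LTED, 79.1% for fulvestrant in HCC-1428/LTED, 50.7% for the difference between the lines, 79.1% between the lines under ethanol and 65.7% for shared changes. At a log2 change of 1 these shares were 100%, 100%, 98.5%, 100% and 98.5%, and at most 7.0% of the calls in any of these simulations were false. A list shifted by -0.5 was the only 1 of 19 lists called in its simulated comparison. In the real comparisons 3177 to 15625 genes were called, far more than the 200 changed here, so the simulated shares need not hold for them. Because the simulated genes were independent, the list check does not cover lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.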

Results

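Gene expression was measured in the lines MCF-7/LTED and HCC-1428/LTED, derivatives of the estrogen receptor-positive breast cancer lines MCF-7 and HCC-1428 that grow under long-term estrogen deprivation (LTED). Cells of each line were treated for 48 h with 1 µM fulvestrant, an antagonist that binds the estrogen receptor and leads to its degradation, or with 0.1% ethanol, its vehicle. Each of the 4 groups had 3 arrays. The series title states an interest in an estrogen receptor-dependent, E2F-directed programme, and the comparisons ask which genes the drug changed in each line and whether the lines differed. Values are log2 RMA levels, and changes are given as log2 fulvestrant minus ethanol ± SE (n = 3 arrays per group) with adjusted p from limma. The median array value was 5.55 to 5.61 in MCF-7/LTED and 5.28 to 5.34 in HCC-1428/LTED. Across genes, the first principal component, with 84.8% of the variance, parted the lines, and the second, with 10.4%, parted fulvestrant from ethanol.

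In MCF-7/LTED, fulvestrant lowered estrogen-induced genes and the genes of DNA replication and mitosis, and raised estrogen-repressed genes. PDZK1, a scaffold protein gene induced by estrogen, fell by 3.99 ± 0.09 (adjusted p = 6.0e-11), from a level of 7.79 ± 0.22 to 3.80 ± 0.03 (SD, n = 3). The end level lay under the lower quartile of these arrays (4.16 to 4.19) and was not shown to be above background, so the fall is read as a lower bound. TP53INP1, a stress-response gene with anti-proliferative action, had the largest rise, 2.80 ± 0.06 (adjusted p = 6.0e-11). All 53 measured E2F target genes fell, with a median change of -1.12, as did all 38 G2/M and mitosis genes, with a median of -1.41. In total 7198 of 19775 genes changed, 3716 up and 3482 down, and 491 of them by at least 1 on the log2 scale, 169 up and 322 down. With each array centred on its own median, the split was 2871 up and 4171 down.

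Among the 30 measured estrogen-induced genes in MCF-7/LTED, 26 fell and 1 rose (median change -1.07, camera adjusted p = 9.2e-19, and adjusted p = 0.0012 with an estimated correlation). MYBL1, which encodes the transcription factor A-MYB, was lower by -2.41 ± 0.09. GREB1, an estrogen-regulated coregulator gene, changed by -1.79 ± 0.10, TFF1, which encodes a secreted trefoil protein, by -1.22 ± 0.07, the progesterone receptor gene PGR by -1.13 ± 0.13 (to a level of 4.33), the chemokine gene CXCL12 by -1.22 ± 0.10 and the growth factor receptor gene IGF1R by -1.34 ± 0.06. The gene that rose was XBP1, a transcription factor of the secretory pathway, by 0.19 ± 0.05 (adjusted p = 0.0092), a call that ended when arrays were centred on their medians (adjusted p = 0.070). The cyclin D1 gene CCND1 changed by -0.17 ± 0.06 (adjusted p = 0.0495), and this call ended when any of 10 of the 12 arrays was left out in turn, all but replicate 1 of each line's fulvestrant group, with an adjusted p up to 0.168. It also ended with the replicate number as a block (adjusted p = 0.112), after quantile normalization of all arrays together (adjusted p = 0.133), without probe sets named _x_at or _s_at (adjusted p = 0.0680) and with the line fitted alone (adjusted p = 0.0678). The other, dimmer probe set of CCND1 fell further, by 0.42 (adjusted p = 0.0038 over probe sets). All 14 estrogen-repressed genes rose (median 1.02, camera adjusted p = 2.4e-14, and adjusted p = 0.0025 with an estimated correlation), among them BCAS1 by 2.05 ± 0.10, the unconventional cyclin gene CCNG2 by 1.56 ± 0.06, the receptor tyrosine kinase gene ERBB2 by 1.29 ± 0.06 and the pro-apoptotic gene BIK by 1.03 ± 0.08. The estrogen receptor transcript itself, ESR1, rose by 0.26 ± 0.04 (adjusted p = 0.00045).

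The E2F target genes of MCF-7/LTED fell between -0.31 and -2.03 each (camera adjusted p = 1.3e-41, and adjusted p = 0.0015 with an estimated correlation), and in all 53 the 3 fulvestrant arrays lay below the 3 ethanol arrays. E2F7, an atypical E2F repressor gene, fell by 2.03 ± 0.11 and MCM10, a replication initiation factor gene, by 1.88 ± 0.07. E2F1 changed by -0.98 ± 0.08 and E2F2 by -1.05 ± 0.07, both activator E2Fs. Of the G2/M and mitosis genes (adjusted p = 0.0025 with an estimated correlation), CDC20, an activator of the anaphase-promoting complex, changed by -1.79 ± 0.07 and the proliferation marker MKI67 by -1.70 ± 0.09. Of 20 homologous recombination and Fanconi genes 18 fell (median -1.07, adjusted p = 0.0041 with an estimated correlation), RAD51AP1 by 1.61 ± 0.07. Of 18 MYC and ribosome biogenesis genes 17 fell (median -0.74, adjusted p = 0.0025 with an estimated correlation), MYC by 0.76 ± 0.06, and the nucleolar protein genes NOP16 by 0.99 ± 0.06 and RRP9 by 0.99 ± 0.10. Of 15 CDK inhibitors and anti-proliferative genes 9 rose and none fell past the threshold (median 0.20, adjusted p = 0.039 with an estimated correlation). CDKN1A, which encodes p21, rose by 0.95 ± 0.08. CDKN1B, which encodes p27, was higher by 0.20 ± 0.06 (adjusted p = 0.023), a call that ended without ethanol replicate 2 (adjusted p = 0.080), without fulvestrant replicate 1 (adjusted p = 0.101), with arrays centred on their medians (adjusted p = 0.115) and with the line fitted alone (adjusted p = 0.0666).

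Other groups moved less evenly in MCF-7/LTED. Of 24 interferon-stimulated genes 13 rose and none fell past the threshold (median 0.38), led by IFIT1, an antiviral RNA-binding protein gene, by 1.5 ± 0.30 and IRF9, a transcription factor of the interferon response, by 1.41 ± 0.14. The list was called at the preset correlation (adjusted p = 3.9e-05) but not with an estimated one (adjusted p = 0.278 with an estimated correlation). Of 17 luminal epithelial markers 12 rose and 1, the trefoil factor gene TFF3, fell by 0.39 ± 0.08 (list adjusted p = 0.00016, and adjusted p = 0.0504 with an estimated correlation). No camera call was made for 10 lists. Of these, the BCL2 family had 5 rises and 4 falls of 15, with BCL2 changed by -0.65 ± 0.07 and the pro-apoptotic PMAIP1 by -2.20 ± 0.12. The receptor tyrosine kinase and PI3K pathway had 11 rises and 5 falls of 23, with PIK3R3, a PI3K regulatory subunit gene, up by 1.30 ± 0.05. The hypoxia genes had 5 rises and 4 falls of 12, with ANKRD37 up by 1.12 ± 0.10 and the glucose transporter gene SLC2A1 changed by -1.19 ± 0.06. The immediate early genes had 7 rises and 3 falls of 12, with EGR1 up by 1.31 ± 0.07. The estrogen receptor and coregulators had 5 rises and 7 falls of 15, the unfolded protein response genes 8 and 7 of 20, the sterol synthesis genes 5 and 2 of 17, the basal and mesenchymal markers 3 and 2 of 14, the leukocyte markers 1 and 0 of 10, and the fibroblast and endothelial markers 0 and 0 of 13. Outside the lists, the largest falls were those of FGFBP2, by 4.32 ± 0.14, and of the amino acid transporter gene SLC6A14, by 4.12 ± 0.16, both to low levels (4.42 and 3.97). SLC6A14 ended under the lower quartile of these arrays, so its fall is again read as a lower bound. The neuropeptide gene GAL fell by 2.32 ± 0.12. VTCN1, which encodes the immune checkpoint ligand B7-H4, rose by 2.37 ± 0.08 and the liprin gene PPFIBP2 by 2.26 ± 0.06.

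For every gene named as risen or fallen in either line, the 3 arrays of a group lay all above or all below the 3 of the other group. This follows largely from how the genes were chosen, since the naming rule required it of the largest changes and it held for 7019 of the 7198 changed genes in MCF-7/LTED and 6280 of 6394 in HCC-1428/LTED, so it lends single genes no further support. Such separation was seen in 45.7% of all genes in MCF-7/LTED and in 45.3% in HCC-1428/LTED, against 10% by chance. The 3′ minus 5′ difference of ACTB was 0.0006 higher with fulvestrant in MCF-7/LTED (exact permutation p = 1.0). The 18S rRNA controls differed by -0.51 in MCF-7/LTED (exact permutation p = 0.2) and by -0.43 in HCC-1428/LTED (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give).

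**Figure D1:**
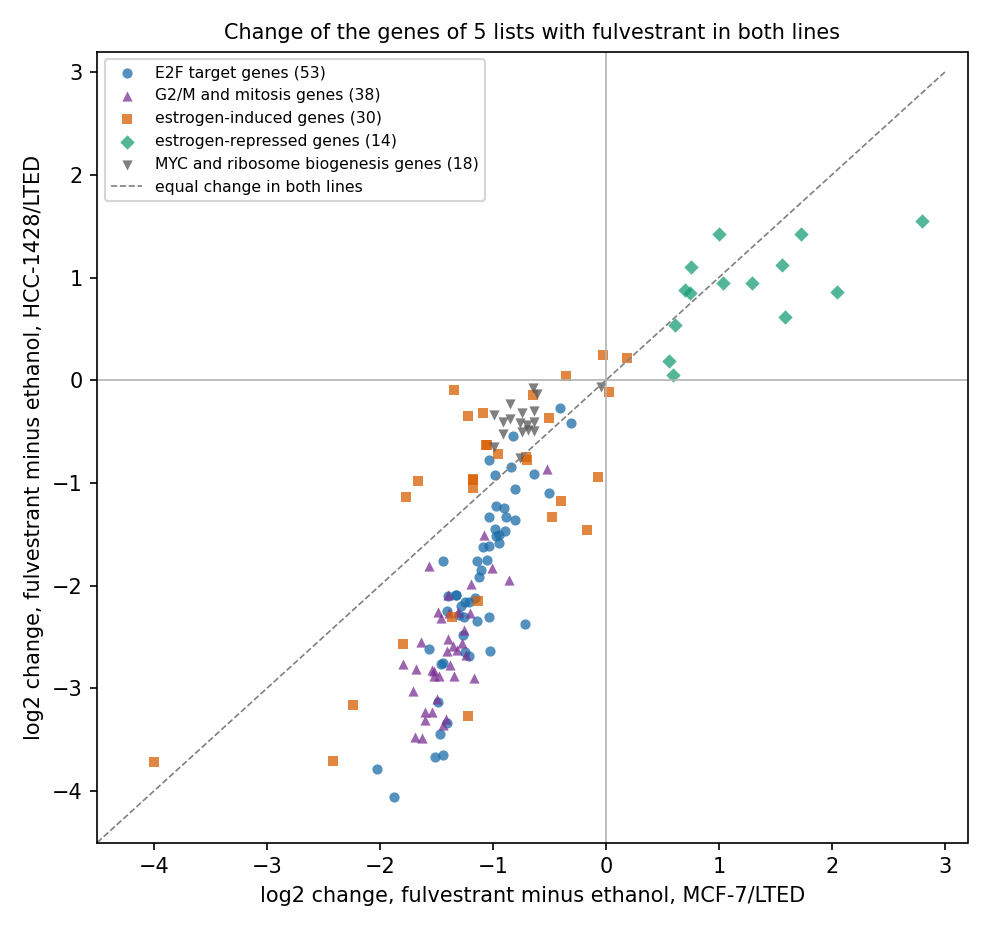
Each point is a gene of 1 of 5 lists, with its log2 change (fulvestrant minus ethanol) in MCF-7/LTED on the x axis and in HCC-1428/LTED on the y axis, and the dashed line marks equal changes. All 53 E2F target and 38 G2/M genes lie below 0 on both axes, most of them below the dashed line, with list medians of -1.12 and -1.41 in MCF-7/LTED and of -2.09 and -2.65 in HCC-1428/LTED.

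In HCC-1428/LTED, fulvestrant lowered the same 53 E2F target genes, with a median change of -2.09, and the same 38 G2/M and mitosis genes, with a median of -2.65, and it lowered most estrogen-induced genes. KRT13, an epithelial keratin gene, had the largest fall, 5.94 ± 0.09 (adjusted p = 2.9e-13), from 10.62 ± 0.11 to 4.68 ± 0.09 (SD, n = 3), and the cytokine gene IL20 fell by 4.95 ± 0.13. HAS3, a hyaluronan synthase gene, had the largest rise by the brightest probe set of each gene, 2.73 ± 0.07 (adjusted p = 9.3e-12), while its other probe set changed by 0.22. In total 6394 genes changed, 3196 up and 3198 down, and 511 of them by at least 1, 97 up and 414 down. After quantile normalization of all arrays together the split was 3938 up and 2879 down. With these falls the 3′ minus 5′ difference of ACTB, a sign of RNA quality, was higher by 0.117 under fulvestrant (exact permutation p = 0.1), and that of GAPDH by 0.0221 (exact permutation p = 0.2).

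The E2F target genes of HCC-1428/LTED fell between -0.27 and -4.06 (camera adjusted p = 1.3e-59, and adjusted p = 0.00052 with an estimated correlation). MCM10 fell by 4.06 ± 0.07, E2F7 by 3.79 ± 0.11 and UHRF1, a gene of DNA methylation maintenance, by 3.64 ± 0.07. E2F1 changed by -1.44 ± 0.08 and E2F2 by -1.75 ± 0.07. Of the G2/M genes (adjusted p = 0.00098 with an estimated correlation), the spindle protein genes DLGAP5 and BUB1 fell by 3.48 ± 0.10 and 3.47 ± 0.07, and MKI67 by 3.02 ± 0.09. All 20 homologous recombination and Fanconi genes fell (median -1.32, adjusted p = 0.0020 with an estimated correlation), the helicase gene BRIP1 by 3.00 ± 0.06 and RAD51AP1 by 2.87 ± 0.07. Of the 18 MYC and ribosome biogenesis genes 15 fell (median -0.41, adjusted p = 0.0095 with an estimated correlation), MYC by 0.76 ± 0.06 and NOP16 by 0.65 ± 0.06.

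Of the 30 estrogen-induced genes in HCC-1428/LTED, 24 fell and 1 rose (median -0.95, camera adjusted p = 1.3e-19, and adjusted p = 0.00052 with an estimated correlation). PDZK1 fell by 3.71 ± 0.09 (to 3.35, under the lower quartile of these arrays, so again a lower bound), MYBL1 by 3.70 ± 0.09, TFF1 by 3.26 ± 0.07, GREB1 by 2.56 ± 0.10, PGR by 2.15 ± 0.13 and CCND1 by 1.46 ± 0.06. CXCL12 changed by -0.34 ± 0.10 (adjusted p = 0.015), a call that ended without ethanol replicate 2 (adjusted p = 0.0619) and with the mean of all its probe sets (adjusted p = 0.0671). IGF1R did not pass the test (-0.10 ± 0.06, adjusted p = 0.248). XBP1 again was the gene that rose, by 0.21 ± 0.05, a call that ended with the mean of its probe sets (adjusted p = 0.0971). Of 14 estrogen-repressed genes 13 rose (median 0.91, adjusted p = 0.0029 with an estimated correlation), TP53INP1 by 1.55 ± 0.06, ERBB2 by 0.94 ± 0.06 and BIK by 0.94 ± 0.08. ESR1 was higher by 0.13 ± 0.04 (adjusted p = 0.0359), a call that ended when ethanol replicate 2 or 3 or any fulvestrant replicate of this line was left out (adjusted p between 0.0510 and 0.135), when the line was fitted alone (adjusted p = 0.0728), with the replicate number as a block (adjusted p = 0.0872) and without probe sets named _x_at or _s_at (adjusted p = 0.0656). Over its 9 probe sets the changes lay between -0.08 and 0.605, with 3 called up and none called down.

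Of the other lists in HCC-1428/LTED, 16 of 24 interferon-stimulated genes rose and 1, OAS3, fell by 0.57 ± 0.10. The list's median was 0.34 (adjusted p = 3.7e-06 at the preset correlation, and adjusted p = 0.237 with an estimated correlation), and IFIT1 rose by 2.29 ± 0.30 and IRF9 by 1.61 ± 0.14. Of 17 sterol synthesis genes 9 fell and 4 rose (median -0.22, adjusted p = 0.016, and adjusted p = 0.205 with an estimated correlation), including EBP and FDPS, which encode enzymes of cholesterol synthesis and fell by 0.89 ± 0.05 and 0.62 ± 0.06. The sterol call also ended with dim genes left out (adjusted p = 0.127). No camera call was made for 11 lists. In the BCL2 family 7 of 15 rose and 6 fell, with BCL2 up by 0.35 ± 0.07 and PMAIP1 changed by -1.95 ± 0.12. In the receptor tyrosine kinase and PI3K pathway 10 of 23 rose and 6 fell, with ERBB4 up by 1.08 ± 0.06 and the phosphatase gene INPP4B, which fell by 0.94 ± 0.08. In the hypoxia list 5 of 12 rose and 3 fell, with ANKRD37 up by 1.42 ± 0.10 and SLC2A1 changed by -1.22 ± 0.06. Among CDK inhibitors and anti-proliferative genes 7 of 15 rose and 4 fell, and CDKN1A fell by 0.67 ± 0.08. CDKN1B did not pass the test (0.15 ± 0.06, adjusted p = 0.083), although it did in 4 alternatives, after quantile normalization of all arrays together (adjusted p = 0.0351), with dim genes left out (adjusted p = 0.0412), with an intensity trend and robust variance (adjusted p = 0.0145) and without MCF-7/LTED fulvestrant replicate 1 (adjusted p = 0.0452). Luminal markers had 10 rises and 5 falls of 17, the unfolded protein response genes 8 and 3 of 20, the estrogen receptor and coregulators 6 and 3 of 15, the immediate early genes 2 and 5 of 12, the basal and mesenchymal markers 2 and 1 of 14, and the leukocyte and the fibroblast and endothelial markers 1 and 0 each. Outside the lists, the potassium channel gene KCNJ13 rose by 2.56 ± 0.06, SOCS2, a suppressor of cytokine signalling, by 2.56 ± 0.08, the carboxypeptidase gene CPB1 by 1.90 ± 0.09 and the nuclear receptor gene NR5A2 by 1.86 ± 0.09, and ID4, an inhibitor of DNA-binding helix-loop-helix factors, fell by 3.64 ± 0.11.

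Adjusted over the list alone, the counts of rises and falls were those over all genes for the E2F target, G2/M, homologous recombination, estrogen-repressed, receptor tyrosine kinase and basal lists in both lines. Elsewhere they moved by at most 2 genes in a direction, except that 20 interferon-stimulated genes rose in HCC-1428/LTED. The mean and median of the basal list in HCC-1428/LTED differed in sign (0.0033 and -0.03, with a test pointing down). Values belong to the brightest probe set of a gene, and other probe sets can differ. The lowest and highest changes over 3 probe sets were -2.41 and 0.04 in MCF-7/LTED for MYBL1, -1.79 and -0.18 for GREB1, and -0.08 and 2.80 for TP53INP1. In HCC-1428/LTED they were -3.70 and 0.25 for MYBL1, -2.56 and 0.07 for GREB1 and, over 5 probe sets, -3.47 and -0.08 for BUB1. Of the 4 probe sets of INPP4B, 1 changed up and 1 down in MCF-7/LTED. Of the 5 of MCM4, 4 fell and 1 rose there, by 0.18.

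The lines shared much of the response. PDZK1, the RNA-binding protein gene RBM24, MYBL1, the transcription factor gene EGR3 and the fatty acid elongase gene ELOVL2 fell in both, RBM24 by 2.82 ± 0.09 in MCF-7/LTED and by 2.68 ± 0.09 in HCC-1428/LTED, EGR3 by 2.24 ± 0.19 and 3.16 ± 0.19, and ELOVL2 by 2.22 ± 0.20 in each. PPFIBP2, the long non-coding RNA DRAIC, TP53INP1, IFIT1 and the bicarbonate transporter gene SLC4A8 rose in both, PPFIBP2 by 2.26 ± 0.06 and 1.93 ± 0.06, DRAIC by 1.71 ± 0.10 and 1.58 ± 0.10, and SLC4A8 by 1.43 ± 0.08 and 1.42 ± 0.08. In total 4052 genes changed the same way, 1830 up and 2222 down, where independent lists of these sizes would share 600.6 and 563.1. Which side was larger depended on the scaling, with 2239 up and 1902 down after quantile normalization of all arrays together, and 1605 up and 2333 down with each array centred on its median. Opposite changes were fewer than such lists would give, with 160 genes up in MCF-7/LTED and down in HCC-1428/LTED against 600.9, and 101 the other way against 562.8. Across all 19775 genes the changes correlated with Pearson's r = 0.686 and Spearman's rho = 0.565, where genes are not independent replicates. The lines have separate control arrays.

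The difference between the lines was tested directly, as the change in HCC-1428/LTED minus that in MCF-7/LTED. Proliferation genes fell further in HCC-1428/LTED. The median difference was -0.76 for E2F target genes, with 45 of 53 lower, 2 higher and adjusted p = 0.0027 with an estimated correlation, and -1.26 for G2/M and mitosis genes, with 36 of 38 lower and adjusted p = 0.0027 with an estimated correlation. The 2 higher were the replication genes MCM4 (0.26 ± 0.07) and RPA2 (0.27 ± 0.07). The MCM4 call ended without MCF-7/LTED fulvestrant replicate 2 or 3, HCC-1428/LTED ethanol replicate 2 or HCC-1428/LTED fulvestrant replicate 2 or 3 (adjusted p between 0.0509 and 0.0562), with the replicate number as a block (adjusted p = 0.0531) and with the mean of all probe sets (adjusted p = 0.0568), and that of RPA2 without MCF-7/LTED ethanol replicate 3, MCF-7/LTED fulvestrant replicate 2 or HCC-1428/LTED fulvestrant replicate 1 (adjusted p between 0.0529 and 0.0539). MYC and ribosome biogenesis genes fell further in MCF-7/LTED, with a median difference of 0.34, 12 of 18 higher and none lower (adjusted p = 0.022 with an estimated correlation). The estrogen-induced genes as a list gave no call (9 higher and 10 lower of 30, camera adjusted p = 0.872, with a median of 0.13, a mean of -0.12 and a test pointing down). In total 3177 genes differed, 1299 higher and 1878 lower in HCC-1428/LTED, 290 of them by at least 1, 56 up and 234 down. With each array centred on its median the split was 1822 higher and 1455 lower.

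Single genes differed in either direction. Background was not measured for single probe sets, so where a line's levels lay near or under the lower quartile of its arrays, the size of the difference is not exact. The amino acid transporter gene SLC6A14 (difference 4.29 ± 0.22) and FGFBP2 (3.92 ± 0.20) fell in MCF-7/LTED, where their ethanol levels were 8.09 ± 0.23 and 8.74 ± 0.31 (SD, n = 3), against 2.63 ± 0.03 and 4.03 ± 0.13 in HCC-1428/LTED. These low levels, against a lower quartile of 3.85 to 3.87, do not allow the drug responses of the lines to be compared for these genes. KRT13 (-5.62 ± 0.12), ID4 (-3.27 ± 0.16), IL20 (-2.85 ± 0.18) and the keratin gene KRT15 (-2.46 ± 0.18) lay at the other end with VTCN1 (-2.52 ± 0.11). VTCN1 had an ethanol level of 10.09 in HCC-1428/LTED, against 5.43 in MCF-7/LTED, where it rose. Whether the higher start mattered was not tested. KRT13 had a level of only 4.01 in MCF-7/LTED under ethanol, so the drug responses of the lines cannot be compared for it either. NR5A2 fell by 1.13 ± 0.09 in MCF-7/LTED and rose in HCC-1428/LTED (difference 2.99 ± 0.13), and the differences of HAS3 and KCNJ13 were 3.02 ± 0.10 and 2.16 ± 0.08, with ethanol levels of 4.31 and 3.72 in MCF-7/LTED. CDKN1A rose in MCF-7/LTED and fell in HCC-1428/LTED (-1.62 ± 0.12), and BCL2 did the reverse (1.00 ± 0.09). The fall of CCND1 was deeper in HCC-1428/LTED (-1.29 ± 0.09), as was that of TFF1 (-2.05 ± 0.09). IGF1R fell in MCF-7/LTED and had no call in HCC-1428/LTED (difference 1.24 ± 0.09). For PGR (-1.01 ± 0.18) and CXCL12 (0.87 ± 0.14) it was not settled which line responded more. PGR went from 5.46 to 4.33 in MCF-7/LTED, near the lower quartile, and from 8.55 to 6.40 in HCC-1428/LTED, and CXCL12 from 5.86 to 4.65 in MCF-7/LTED and from 4.80 to 4.45 in HCC-1428/LTED, so that the line with the smaller fall started lower. GREB1 (-0.77 ± 0.13) and E2F2 (-0.70 ± 0.10) lost the call with the mean of all probe sets (adjusted p = 0.194 and 0.0514). Of the other lists, those of homologous recombination and Fanconi (median -0.29, adjusted p = 0.049 with an estimated correlation), sterol synthesis (-0.27, adjusted p = 0.032 with an estimated correlation) and immediate early genes (-0.23, adjusted p = 0.049 with an estimated correlation) were lower in HCC-1428/LTED. The estrogen-repressed genes (-0.33), CDK inhibitors (-0.24), luminal markers (-0.15) and estrogen receptor and coregulators (0.14) were called at the preset correlation but not with an estimated one (adjusted p = 0.087, 0.071, 0.087 and 0.070 with an estimated correlation). With genes of several lists left out, the call also ended for the estrogen-repressed genes (adjusted p = 0.184) and the estrogen receptor and coregulators (adjusted p = 0.112). Adjusted over the list alone, 47 E2F target genes, 38 G2/M genes and 10 sterol synthesis genes were lower, 15 MYC and ribosome biogenesis genes were higher, and 13 homologous recombination genes were lower and 3 higher. The BCL2 family, receptor tyrosine kinase, basal, fibroblast, leukocyte, interferon, unfolded protein response and hypoxia lists gave no call, and for the receptor tyrosine kinase list the median was -0.04, the mean 0.01 and the test pointed down.

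**Figure D2:**
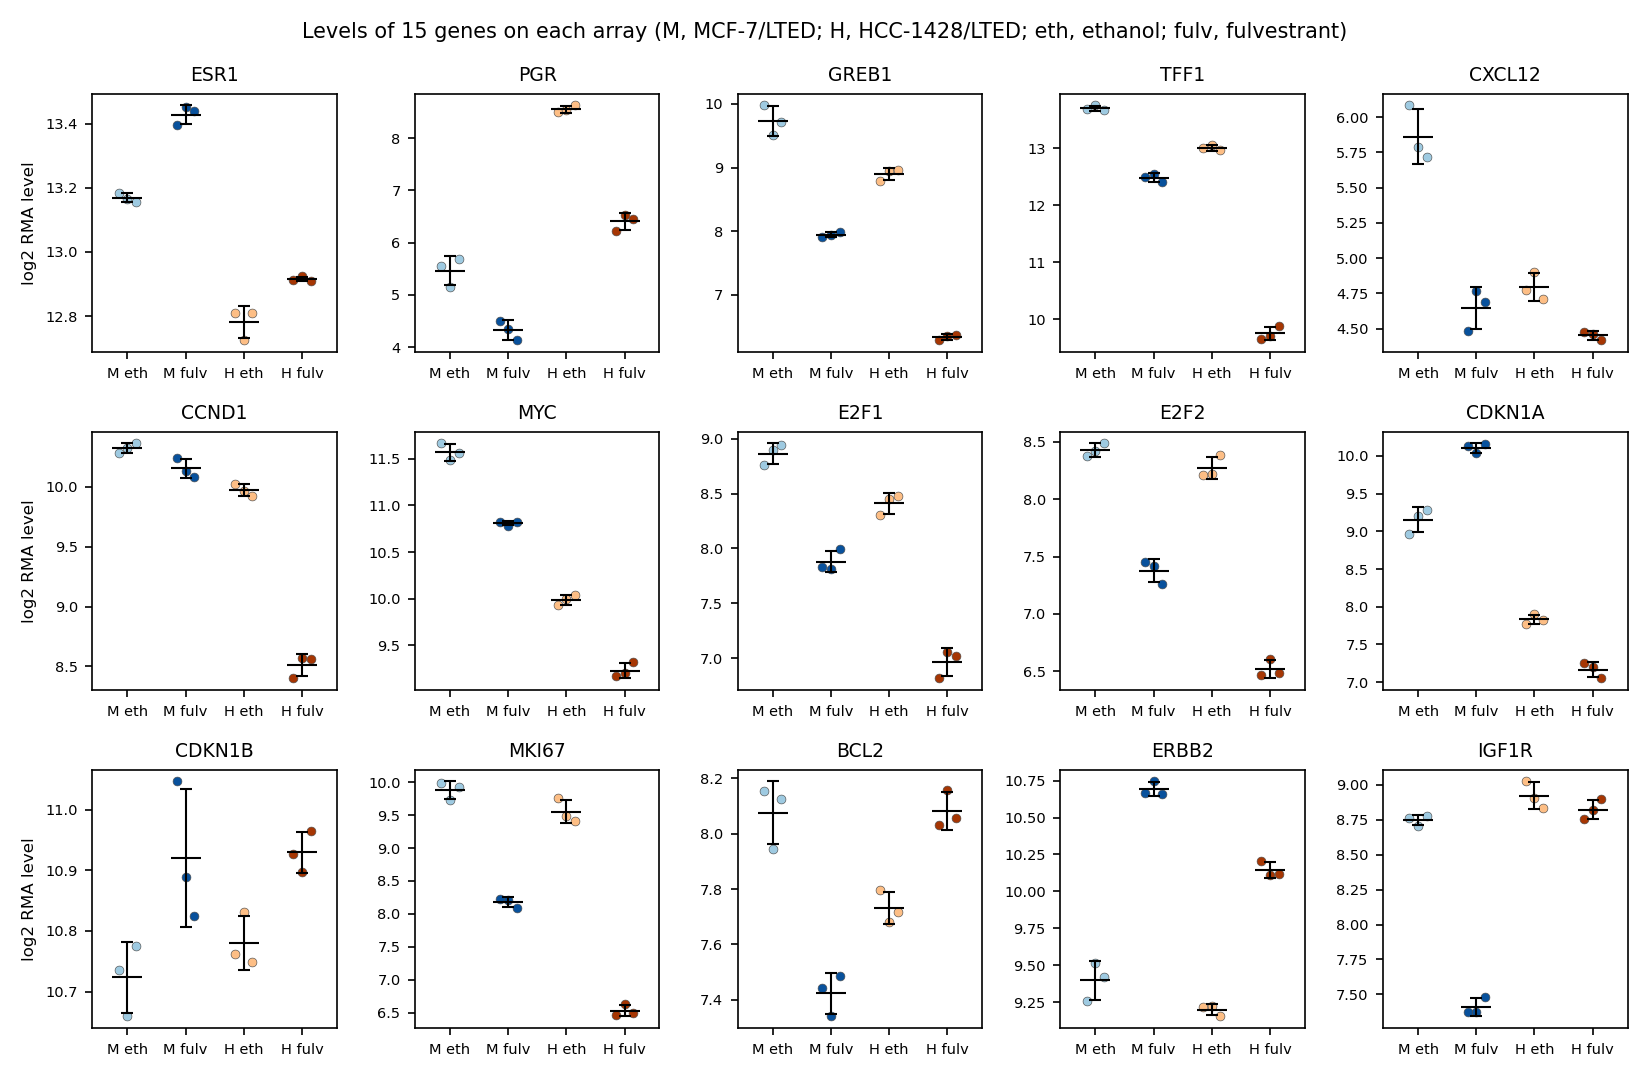
Points are the log2 RMA levels of the 15 panel genes on each of the 3 arrays per group, with the mean as a bar and the SD as whiskers, and each gene has its own y axis that does not start at 0. CDKN1A rises with fulvestrant in MCF-7/LTED (0.95) and falls in HCC-1428/LTED (-0.67), while TFF1, MKI67 and E2F1 fall in both lines.

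Under ethanol the lines differed in most genes. The median of all genes was -0.33 lower in HCC-1428/LTED, a shift of the whole distribution, and the differences of genes and the list median below are relative to it, while the counts are not. The cancer-testis antigen gene MAGEA6 was higher in HCC-1428/LTED by 9.69 ± 0.11 (SE, n = 3), although its probe set is of a kind that can share probes with related genes of its family. The angiotensin receptor gene AGTR1 was higher by 9.19 ± 0.06, CLCA2 by 8.21 ± 0.12 and the iron exporter gene SLC40A1 by 7.95 ± 0.08. The mean levels of these 4 genes in MCF-7/LTED were 3.56, 3.38, 3.49 and 3.08, below the lower quartile of that line's ethanol arrays (4.14 to 4.17), against 12.91, 12.24, 11.37 and 10.70 in HCC-1428/LTED. ID1, an inhibitor of DNA-binding helix-loop-helix factors, was lower in HCC-1428/LTED by -8.68 ± 0.11, the WNT antagonist gene DKK1 by -6.93 ± 0.09, FREM2 by -6.42 ± 0.07, the coagulation inhibitor gene TFPI by -6.34 ± 0.09 and BASP1 by -6.19 ± 0.09. Their mean levels in HCC-1428/LTED were 4.07, 3.86, 2.85, 3.44 and 4.41, with those of ID1 and BASP1 above and the other 3 near or below the lower quartile of its ethanol arrays (3.85 to 3.87), against 13.08, 11.11, 9.59, 10.11 and 10.94 in MCF-7/LTED. Signal and background were not separated for these low levels, and the SE covers only the spread between arrays. Of the 19 lists only that of MYC and ribosome biogenesis was called, at a median of -0.79 relative to all genes (adjusted p = 0.0026, and adjusted p = 0.640 with an estimated correlation). In total 15625 genes differed, 3473 higher and 12152 lower in HCC-1428/LTED, 3894 of them by at least 1, all without the median shift taken off. With arrays centred on their medians 14113 differed, 6429 higher and 7684 lower, 3058 of them by at least 1, and after quantile normalization of all arrays together 14030 differed, 6912 higher and 7118 lower. A difference between the lines and a difference in the processing of their arrays cannot be told apart here.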

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

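The tests of a common normalization and of a single scale factor for the cell cycle genes, the splits with the shared change removed, the mark for low levels, and the choice of WIPI1, ABAT, ZFP36L2, LRP4 and ZBTB2, were made only after the result was seen. Except for the ethanol comparison, the results in this part stand out because the fulvestrant change differed between the lines by a direct test of the difference, given below as the HCC-1428/LTED minus the MCF-7/LTED log2 change.

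In total 3177 genes differed. Of 100 drawn splits of the arrays among 200 possible ones, 2 gave as many genes, the real one included. These splits decide nothing about the count, because mixed groups take the change shared by both lines into the spread within groups, and the highest other split, with 8723 genes, turns over the fulvestrant and ethanol labels of 1 line, so that shared changes count as differences. The next highest gave 3061. With each gene's mean change of both lines first subtracted from the fulvestrant arrays, 1 of the same 100 splits, the real one, gave as many as 3177 genes. The highest other gave 0, so the share was under 0.05. This does not decide on chance either, because the difference itself stays in the arrays. Mixed groups take it into the spread within groups, and turning over the labels of 1 line cancels it, so low counts in the other splits were built in. For the counts of 7198 genes in MCF-7/LTED, 6394 in HCC-1428/LTED and 15625 between the lines, 1 of 10 splits, the real one, gave as many, the highest other gave 0, and 10 splits are too few for a share under 0.05.

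Cell cycle genes fell further in HCC-1428/LTED, with a median difference of -0.97 over the 91 genes of the E2F target and G2/M lists (quartiles -1.40 and -0.59). After quantile normalization of the gene values of all arrays together the median was -1.05 (quartiles -1.43 and -0.62). This argues against unequal distributions of these values as the whole cause. The probe-level steps of RMA were not redone, so it cannot decide on their separate use for each line. A single scale factor for all changes would make the other shared falls deeper too, but the MYC and ribosome biogenesis genes differed by a median of 0.34 (quartiles 0.23 and 0.48). The homologous recombination and Fanconi genes, which also fell in both lines, did fall further in HCC-1428/LTED, by a median of -0.29. The MYC list started lower in HCC-1428/LTED, at a median of -0.79 relative to all genes, and like starting levels were not tested for it. Over the 37 cell cycle genes with ethanol levels within 0.5 of each other after the median shift, the median was -1.05 (quartiles -1.40 and -0.64), which argues against different starting levels. RNA quality, with an ACTB 3′ minus 5′ difference 0.117 higher under fulvestrant in HCC-1428/LTED, was not tested as a cause and stays open. The difference between the changes of the lines was tested directly, but its source was not. A difference between the lines in their response to the drug may account for the pattern. It cannot be told apart here from a difference in how the arrays of the lines were processed.

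More genes were lower than higher in HCC-1428/LTED under ethanol, 12152 against 3473. The dimmest 20% of genes by mean level, 3955 genes, had a median difference of -0.25 (quartiles -0.46 and -0.05), against -0.33 over all genes. These genes were taken to lie mostly near background, which was not measured. If so, their shift by most of the median shift is what separate normalization of the lines predicts, and it may account for the uneven split. The split became 6912 higher and 7118 lower after quantile normalization of all arrays together. That step gives all arrays the same distribution, so a nearly even split follows whatever the cause and does not bear on it. Whether the lines also differ in how many genes they express was not tested.

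The lists that differed had medians of -0.76 for E2F target genes, -1.26 for G2/M and mitosis genes, -0.29 for homologous recombination and Fanconi genes, -0.33 for estrogen-repressed genes, -0.24 for CDK inhibitors and anti-proliferative genes, 0.14 for the estrogen receptor and coregulators, -0.15 for luminal epithelial markers, -0.27 for sterol synthesis genes, 0.34 for MYC and ribosome biogenesis genes and -0.23 for immediate early genes. With an estimated correlation the call ended for the estrogen-repressed genes (adjusted p = 0.087), the CDK inhibitors and anti-proliferative genes (adjusted p = 0.071), the estrogen receptor and coregulators (adjusted p = 0.070) and the luminal markers (adjusted p = 0.087).

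Among cell cycle and repair genes, the differences were -0.46 for E2F1, -0.70 for E2F2, -1.76 for E2F7, -2.18 for MCM10, -2.20 for UHRF1, -1.32 for MKI67, -0.97 for CDC20, -1.85 for DLGAP5, -1.79 for BUB1, -1.26 for RAD51AP1 and -1.86 for BRIP1, with MCM4 at 0.26 and RPA2 at 0.27. Among estrogen-induced genes they were -1.01 for PGR, -0.77 for GREB1, -2.05 for TFF1, -1.29 for CCND1, -1.29 for MYBL1, -0.93 for EGR3, 0.87 for CXCL12 and 1.24 for IGF1R. Among estrogen-repressed genes they were -0.35 for ERBB2, -1.25 for TP53INP1, -1.18 for BCAS1 and -0.44 for CCNG2.

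Of the other genes lower in HCC-1428/LTED, the differences were -1.62 for CDKN1A, -2.52 for VTCN1, -0.33 for PPFIBP2, -0.999 for PIK3R3, -1.17 for EGR1, -5.62 for KRT13, -2.85 for IL20, -3.27 for ID4, -0.71 for OAS3, -0.90 for INPP4B, -2.46 for KRT15, -0.47 for TFF3, -1.90 for WIPI1, -1.70 for ABAT and -1.81 for ZFP36L2. Of those higher, they were 1.00 for BCL2, 3.92 for FGFBP2, 4.29 for SLC6A14, 1.88 for GAL, 0.34 for NOP16, 0.65 for RRP9, 3.02 for HAS3, 2.16 for KCNJ13, 1.44 for SOCS2, 2.99 for NR5A2, 1.93 for CPB1, 2.04 for LRP4 and 1.75 for ZBTB2.

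For 11 of these genes (PGR, CXCL12, FGFBP2, SLC6A14, GAL, E2F7, HAS3, KCNJ13, CPB1, KRT13 and EGR3) the mean of at least 1 group lay under the lower quartile of its arrays or less than 0.5 above it. Background was not measured for single probe sets, so the sizes of these differences are not exact. For PGR, CXCL12, FGFBP2, SLC6A14, GAL and KRT13 the line with the smaller fall or none started at the lower level. For these genes a difference in drug response cannot be told from a limit on how far low levels can fall. Whether a higher starting level limited the rise of genes in a line, such as VTCN1 in HCC-1428/LTED, was not tested.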

How the results depend on the processing

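No list called by camera and no change of a named gene reversed its direction in the alternatives run for it. Lists without a call did, among them the BCL2 family and the hypoxia genes of MCF-7/LTED, for which fry pointed the other way. Lists were not rerun after quantile normalization, without probe sets named _x_at or _s_at, or with each line fitted alone. Nor were they rerun with an intensity trend or array weights. Under ethanol only the other list tests were run for them. The differences between the lines of some named genes, among them MCM10, UHRF1, BUB1, BRIP1 and TP53INP1, were not rerun. The side with more genes also turned over in counts. In MCF-7/LTED 3716 up and 3482 down became 2871 and 4171 with arrays centred on their medians, 3480 and 3493 with dim genes left out, and 3158 and 3239 without ethanol replicate 1. For the difference between the lines 1299 higher and 1878 lower became 1822 and 1455 with arrays centred. For shared changes 1830 up and 2222 down became 2239 and 1902 after quantile normalization of all arrays, and in HCC-1428/LTED the even 3196 and 3198 became 3938 and 2879. How many genes moved each way thus rests in part on the scaling of the arrays. Panel genes were left out of the ethanol comparison after some of their differences between the lines were seen to change sign with the scaling of the arrays. That no named gene reversed thus follows in part from this choice and does not cover panel genes in that comparison. The counts of changed genes stayed within 1.5 times those reported, except that 10359 genes differed between the lines under ethanol when dim genes were left out, where 11865 genes were tested. Leaving out each of the 12 arrays in turn gave 6397 to 7164 genes in MCF-7/LTED, 5450 to 6537 in HCC-1428/LTED, 3595 to 4025 changed the same way, 2632 to 3108 that differed between the lines in their change and 15022 to 15680 under ethanol. The medians then ranged from -1.14 to -1.09 (MCF-7/LTED) and -2.09 to -2.04 (HCC-1428/LTED) for E2F target genes, and from -1.10 to -1.04 and -0.97 to -0.91 for estrogen-induced genes. With the replicate number as a block the counts were 6900, 6021, 3805, 2657 and 15558, in the same order. The deviations of arrays with the same number correlated across genes between -0.125 and 0.142, and those of the others between -0.185 and 0.163. No pairing by number was seen, but so few arrays cannot exclude it. In the 3 fulvestrant contrasts an estimated correlation ended 8 of 27 list calls and fry added 17. Under ethanol it ended the only call, and fry, which does not compare with other genes, added 18. Leaving out genes of several lists added the immediate early genes (adjusted p = 0.0201) and the receptor tyrosine kinase and PI3K pathway (adjusted p = 0.0357) in MCF-7/LTED. Leaving out dim genes added the latter list too (adjusted p = 0.0357) and moved its median from 0.11 to 0.24. The cause of these changes was not tested. The number of arrays and, for dim genes, the signal over background limit what can be called.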

Other observations

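The genes in the first paragraph were chosen after their values were seen. A set of 160 genes rose in MCF-7/LTED and fell in HCC-1428/LTED, and 101 did the reverse. WIPI1, an autophagy gene, changed by 1.23 in MCF-7/LTED and -0.67 in HCC-1428/LTED, ABAT, which encodes the enzyme that breaks down GABA, by 1.03 and -0.67, and ZFP36L2, an RNA-binding protein gene, by 0.76 and -1.04. LRP4 changed by -0.67 and 1.38, and the zinc finger gene ZBTB2 by -0.79 and 0.96. Of the 3177 genes whose change differed, 411 fell in both lines and further in HCC-1428/LTED, and 252 fell in both and further in MCF-7/LTED.

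Genes that lie near each other along a chromosome differed alike between the lines under ethanol. Across 19698 genes, which are not independent replicates, the difference between genes 10 apart correlated with Spearman's rho = 0.109 (permutation p = 0.001, the smallest that 1000 shuffled orders can give), against 0.0012 for the fulvestrant change in MCF-7/LTED (permutation p = 0.853) and 0.0093 in HCC-1428/LTED (permutation p = 0.195). At 1 gene apart the fulvestrant changes correlated beyond shuffled orders too, with rho = 0.0480 in MCF-7/LTED and 0.0604 in HCC-1428/LTED (permutation p = 0.001 each), against 0.194 for the difference under ethanol. At 5 apart the change in HCC-1428/LTED correlated with 0.0219 (permutation p = 0.005), within the range of the shuffled orders, whose highest was 0.0295, against 0.100 under ethanol. A hypothesis is that copy number or other regional differences between the lines may contribute. These cannot be separated with expression values alone.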
